A study of Mus musculus with 6 samples.

How the data were processed

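Total RNA from the epididymal white adipose tissue of male C57BL/6J mice aged 20 weeks on a normal diet was sequenced in 6 libraries, 3 labelled wild type (WT) and 3 labelled ZFP251 knockout (KO). Per the labels' protocols, RNA was extracted with TRIzol, assessed on a Bioanalyzer and made into libraries with a stranded mRNA kit, and the design text names the wild-type mice as littermates. Per the submitters' processing notes, STAR 2.5.4, Cufflinks and Cuffdiff 2.2.1 were used with the mouse build mm10. The annotation, filters and library normalization are not given in the sources used here. No label says that every library came from a separate mouse, so p-values measure the spread between these libraries, which may be partly technical.

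The deposited table holds 1 column per library, which the authors made without pooling replicates, and its values were read as FPKM (fragments scaled by transcript length and by the mapped total). No header names the unit: it was inferred from the tools in the processing notes and from the values, which are not whole and whose column sums differ. How depth was scaled is not given. If by the mapped total, a change in a few abundant genes moves the values of the others. The table pairs gene symbols with RefSeq and Ensembl identifiers. It holds no fold changes or p-values, so the authors' Cuffdiff calls were not analysed here. Count-based tests were not run, because the table holds no counts.

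Of 21853 rows, 24 repeated a symbol and the row with the highest mean was kept, which left 21829 genes. The 12539 genes with a mean of at least 1 FPKM over the 6 libraries were tested. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with group as the only term and a mean-variance trend, at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are given as KO minus WT. For Zfp251 an exact permutation test, two-sided, was run on the FPKM values, and with 3 libraries against 3 its smallest p is 0.1.

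Before the data were examined, the groups, the tests, the alternatives, 36 gene lists and the rule for named genes were fixed. Lists with at least 5 tested members were tested with camera, two-sided, with a preset correlation of 0.01, adjusted over 35 lists. The mitochondrially encoded list had no tested member. Camera with an estimated correlation and fry were the alternatives. The named genes were Zfp251, the 6 genes with the smallest p in each direction if none passed the threshold (leaving out predicted genes, Riken clones, pseudogenes, small RNAs and immune receptor segments), up to 4 members with the smallest p of each list, 12 fixed adipose genes, and any gene past the threshold within 1 Mb of Zfp251. Genes named outside that rule were chosen after their values were seen.

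Low FPKM values were compared between libraries to learn their relative depth, since 1 fragment is worth more FPKM in a shallower library. Among genes between 0.03 and 0.12 FPKM in both libraries, the commonest step gave depths relative to WT 1 of 0.79 for WT 2, 0.829 for KO 1, 0.651 for KO 2 and 0.946 for KO 3. At that step lay between 15.3% and 21.8% of those genes, within 0.05 on the log2 scale. In WT 3 the highest share was 12.1% and no depth was taken from it. Total depth is unknown, so no counting intervals are given.

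Gene length, GC content and positions came from GENCODE vM21 on GRCm38, the same assembly as mm10, and all 12539 tested genes had a length. The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, no mean-variance trend, sample weights, each library left out in turn and the replicate number as a block. The median-ratio factors ran from 0.983 in KO 2 to 1.03 in WT 3, so that scaling changed the values little. After the data were seen, a length and GC correction, a covariate for ciliated cells and 3 marker lists were added. The lists were multiciliated cell, tubule epithelium and caput epididymis. The fit was tested on simulated data made from the real genes' means and residual spread, with 200 of 12539 genes changed between KO and WT. It recovered 56% of the 50 genes changed 2-fold, 84% of the 50 changed 4-fold and 100% of the 50 changed 8-fold, with 11 false calls. The simulated noise was independent between genes. In the real libraries a single component of variation held 65.65% of the variance, so these shares check the fit and do not give its power here.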

Results

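RNA from epididymal white adipose tissue, the visceral fat pad beside the testis, was compared between 3 libraries labelled ZFP251 KO and 3 labelled WT, from male mice aged 20 weeks. The design asks what the zinc finger protein ZFP251 does in this tissue. Between 11814 and 12813 genes per library had at least 1 FPKM. The FPKM of all genes summed to 472120, 468499 and 637902 in WT 1, WT 2 and WT 3, and to 426966, 428924 and 439354 in KO 1, KO 2 and KO 3. The 3 adipocyte genes Cfd, Car3 and Fabp4, chosen after their values were seen, took between 6.88% and 12.2% of these sums, the highest share being that of WT 3.

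Zfp251, the targeted gene, was measured first because it checks the labels, and it went against them. Its level was 6.27 ± 0.359 FPKM (SD, n = 3) in the libraries labelled KO and 3.41 ± 0.408 FPKM (SD, n = 3) in WT. The single values were 6.48, 5.86 and 6.48 FPKM in the libraries labelled KO against 3.73, 3.56 and 2.95 FPKM in WT, a ratio of means of 1.84. The log2 difference was 0.72 with a standard error of 0.12, and limma's adjusted p was 0.223, which did not pass the threshold. An exact permutation test gave p = 0.1, the smallest this design allows. The gene (ENSMUSG00000022526) lies on the minus strand of chromosome 15, from 76851609 to 76871435 in GRCm38. A gene-level FPKM does not show which exons were read, and the labels do not give the allele. Every direction below is therefore that of the libraries labelled KO.

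No gene passed limma's adjusted threshold between the groups, out of 12539 tested. The smallest adjusted p was 0.223. At an unadjusted p under 0.05 there were 1700 genes, 1145 with higher and 555 with lower values in the libraries labelled KO, where chance alone gives about 627. The share with higher values among them was 67.4%. It was 79.8% without KO 1, 78.7% without KO 2 and 72.7% with median-ratio scaling. It was 56.2% after quantile normalization, 52.1% without WT 2 and 49.4% with sample weights. After a length and GC correction it was 48.8%, and at a mean of at least 5 FPKM 47.5%. The count was 866 without KO 1, 882 without KO 2, 974 at a mean of at least 5 FPKM, 3914 with sample weights and 170 with a ciliated-cell covariate, where the share was 42.9%. That covariate was added because epithelial transcripts moved with the groups. Its scores were 1.92, 0.452 and 0.438 in WT 1, WT 2 and WT 3. In KO 1, KO 2 and KO 3 they were 2.95, 3.01 and 2.11, so the covariate is partly confounded with group. In 2789 genes (22.2%) the groups did not overlap, where chance gives 10% on average. Genes that move together widen the range around these chance values, and overlap was not counted for other groupings of the libraries. Without WT 1, 482 genes passed, 469 with higher values, and with sample weights 970 passed, 511 with higher values. Among the 469 were 38 multiciliated and 20 tubule epithelium genes, from lists chosen after the data were seen.

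The genes with the smallest p and higher values in the libraries labelled KO, none past the adjusted threshold, included Mest, an imprinted gene tied to adipocyte enlargement. Mest stood at 120 ± 20.2 FPKM (SD, n = 3) against 31.8 ± 12.2 FPKM in WT. Kcnq1, a potassium channel subunit, stood at 3.92 ± 0.591 against 1.35 ± 0.13 FPKM. B3gnt8, a glycosyltransferase, had 5.96 ± 0.316 against 2.81 ± 0.537 FPKM. Shisal2a had 2.09 ± 0.348 against 0.145 ± 0.155 FPKM, and Chad, a cartilage matrix protein, had 5.15 ± 1.75 against 0.363 ± 0.628 FPKM. Chad had 1.09 FPKM in WT 1 and a listed 0 in WT 2 and WT 3. The epithelial gene Epcam, given below, also had more in WT 1 than in WT 2 and WT 3. Whether Chad RNA came from epithelium was not tested. Zfp251 itself was the 6th of these genes.

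The genes with the smallest p and lower values in the libraries labelled KO also missed the adjusted threshold. Pon1, a lipoprotein-associated esterase, had 3.77 ± 0.848 FPKM (SD, n = 3) against 15.7 ± 3.54 FPKM in WT, a log2 difference of -1.80. S100a9 and S100a8, the paired calcium-binding proteins of neutrophils, had log2 differences of -2.84 and -1.70. Cxcl13, a B cell attractant, stood at 1.74 ± 0.374 against 10.2 ± 4.67 FPKM. Retsat, which saturates retinol, stood at 54.2 ± 4.22 against 84.5 ± 4.49 FPKM. Serpina3b, a serine protease inhibitor, stood at 7.34 ± 2.82 against 28.5 ± 9.71 FPKM.

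**Figure D1:**
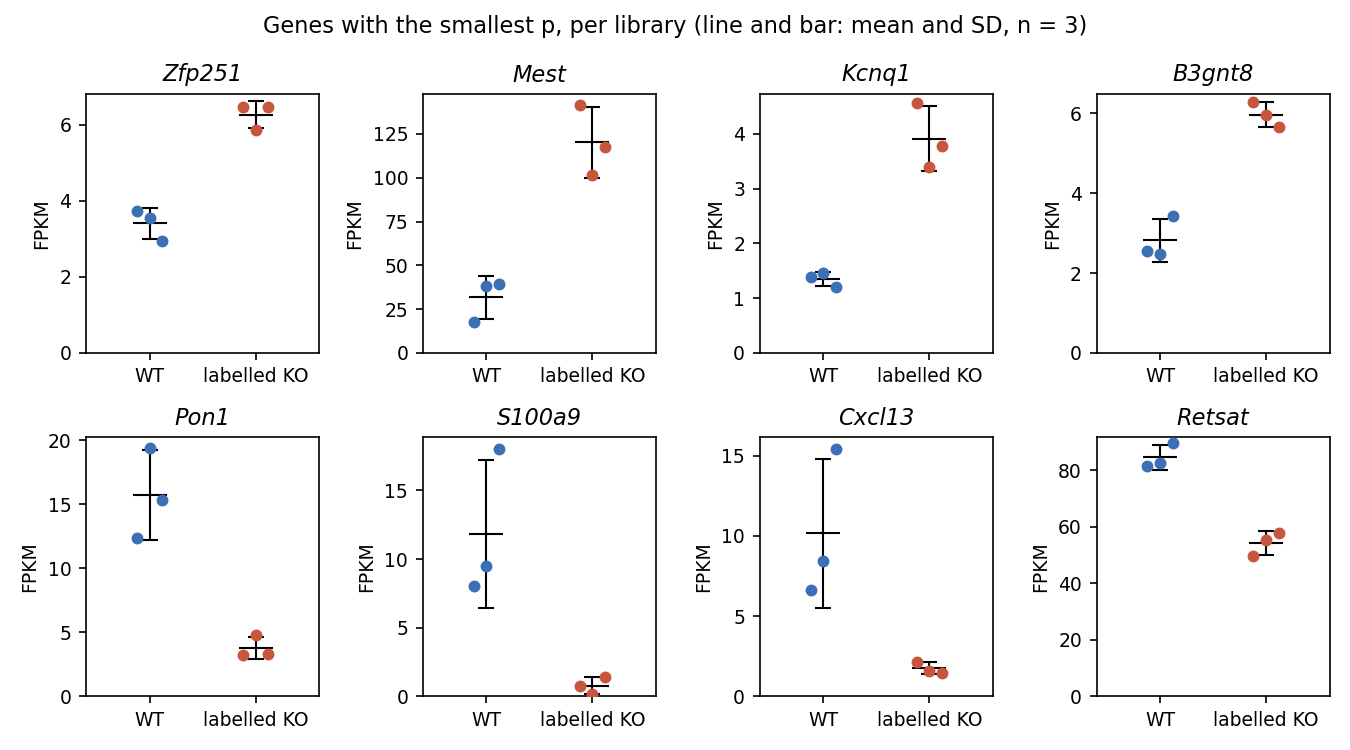
FPKM of Zfp251 and 7 genes with the smallest p in each library, by group (points: libraries; line and bar: mean and SD, n = 3 per group). Zfp251 lay at 5.86 FPKM or more in the 3 libraries labelled KO and at 3.73 FPKM or less in the 3 labelled WT.

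The genes of mature fat cells fell as a group in the libraries labelled KO, with no single gene past the adjusted threshold. With an estimated correlation the adjusted p was 0.726 for the adipocyte list and 0.692 for lipolysis. Of 23 tested markers of mature adipocytes, 20 were lower, with a median log2 difference of -0.39 (camera adjusted p = 0.00242). The lipid droplet gene Cidec had a log2 difference of -0.49, and Pnpla2, the first triglyceride lipase, one of -0.43. Adipoq, which encodes adiponectin, stood at 2269 ± 206 FPKM (SD, n = 3) against 3842 ± 1773 FPKM, a log2 difference of -0.67 and, without WT 3, of -0.32. All 24 genes of lipolysis and fatty acid handling were lower (median -0.28, camera adjusted p = 6.34e-04), among them the lipase inhibitor Angptl4 at -0.50. Adjusted over the list alone no member of either passed. With the ciliated-cell covariate the camera adjusted p was 0.582 and 0.101, and with quantile normalization it was 0.592 and 0.852.

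Genes of mitochondrial fuel use fell as lists too. With an estimated correlation the adjusted p was 0.83 for oxidative phosphorylation and 0.726 for fatty acid oxidation. All 48 genes of oxidative phosphorylation were lower in the libraries labelled KO (median -0.45, camera adjusted p = 2.27e-07), and 22 of 24 genes of fatty acid oxidation (median -0.39, camera adjusted p = 5.37e-05). Ndufs1, a subunit of complex I, had a log2 difference of -0.48, and of -0.29 without WT 3, and Ehhadh, of peroxisomal oxidation, one of -1.04. Cpt1a, which admits fatty acids to mitochondria, had 0.43. Adjusted over the list alone 0 genes of either passed. With the ciliated-cell covariate the median of oxidative phosphorylation was -0.09 (camera adjusted p = 0.175) and that of fatty acid oxidation was -0.15 (camera adjusted p = 0.0292). Without WT 3 the median of oxidative phosphorylation was -0.12 and that of fatty acid oxidation was -0.20. In the same order the medians were -0.165 and -0.213 with quantile normalization, and -0.242 and -0.294 with sample weights.

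Among blood and immune cell markers, the interferon response, erythroid, neutrophil, macrophage and B cell lists fell in the libraries labelled KO. With an estimated correlation the adjusted p was 0.692 for the interferon and neutrophil lists, 0.721 for erythroid, 0.83 for macrophage and 0.709 for B cell. All 7 tested erythroid genes were lower (median -1.23, camera adjusted p = 1.81e-04), among them Alas2, of heme synthesis, at -1.23, and 6 passed when adjusted over the list alone. All 6 tested of 14 neutrophil genes were lower (median -0.83, camera adjusted p = 3.77e-04), 3 of them past the threshold adjusted over the list alone. With no filter on low values the neutrophil median was -0.40. Of 28 interferon response genes 26 were lower (median -0.27, camera adjusted p = 3.89e-05), with 1 past the threshold adjusted over the list alone; Isg15, a ubiquitin-like modifier, had -0.67. Of 26 macrophage genes 25 were lower (median -0.29, camera adjusted p = 6.19e-04), with 3 past the threshold adjusted over the list alone, and Mrc1, a mannose receptor, had -0.48. All 7 tested of 20 B cell genes were lower (median -0.49, camera adjusted p = 0.00486), with 0 past the threshold adjusted over the list alone. With no filter on low values the B cell median was -0.31. Without WT 2 the camera adjusted p was 0.079 for both the macrophage (median -0.16) and B cell lists, and without KO 3 the macrophage median was -0.50. With the ciliated-cell covariate the macrophage median was 0.36 (camera adjusted p = 0.00139) and the neutrophil and B cell lists had a camera adjusted p of 0.175 and 0.893, and the erythroid median was -0.53. The B cell list had a median of -0.43 after the length and GC correction (camera adjusted p = 0.0536) and of -0.30 with sample weights (camera adjusted p = 0.141).

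General epithelial genes and the genes of mural cells, proliferation and the circadian clock rose as lists in the libraries labelled KO. With an estimated correlation the adjusted p was 0.692 for the epididymis and clock lists, 0.726 for proliferation and 0.83 for mural cell. The epithelial genes were the 5 tested of 28 members of the list fixed for the epididymis epithelium, Epcam, Cdh1 and Pax8 with Lcn2 and Clu (median 2.41, camera adjusted p = 0.00108), and 4 passed adjusted over the list alone. The 23 other members, genes of the caput epididymis, were below the filter. With no filter on low values the median of this list was 0.05 (camera adjusted p = 0.00603), and with sample weights it was 1.14 (camera adjusted p = 0.0434). Epcam, an epithelial adhesion molecule, had 30.8, 34.3 and 16.4 FPKM in KO 1, KO 2 and KO 3. It had 14.2 FPKM in WT 1 and 0.199 and 0.191 FPKM in WT 2 and WT 3. The 19 tested proliferation genes had a median of 0.27 (camera adjusted p = 2.89e-04), with Stmn1, a microtubule regulator, at 0.93, and a median of 0.14 without WT 3 and 0.16 without KO 3. The 19 clock genes also had a median of 0.27 (camera adjusted p = 0.00108), with the repressor Cry1 at 0.55 and Per2 at 0.86 (0.57 without WT 1), and the median was 0.47 without KO 3. KO 3 lay among the WT libraries in Per2, with 8.47 FPKM against 4.68, 9.76 and 8.96 FPKM in WT 1, WT 2 and WT 3, and KO 1 and KO 2 had 18.9 and 18.3 FPKM. The 15 mural cell genes had a median of 0.40 (camera adjusted p = 0.0141), with the pericyte proteoglycan Cspg4 at 0.76, and without WT 3 the median was -0.13 (camera adjusted p = 0.821). No proliferation, clock or mural cell gene passed adjusted over the list alone. With the ciliated-cell covariate the camera adjusted p was 0.253 for the epididymis list and 0.822 for mural cell. With sample weights it was 0.0649 for mural cell and 0.16 for proliferation, and with quantile normalization it was 0.616 for proliferation (median -0.01).

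**Figure D2:**
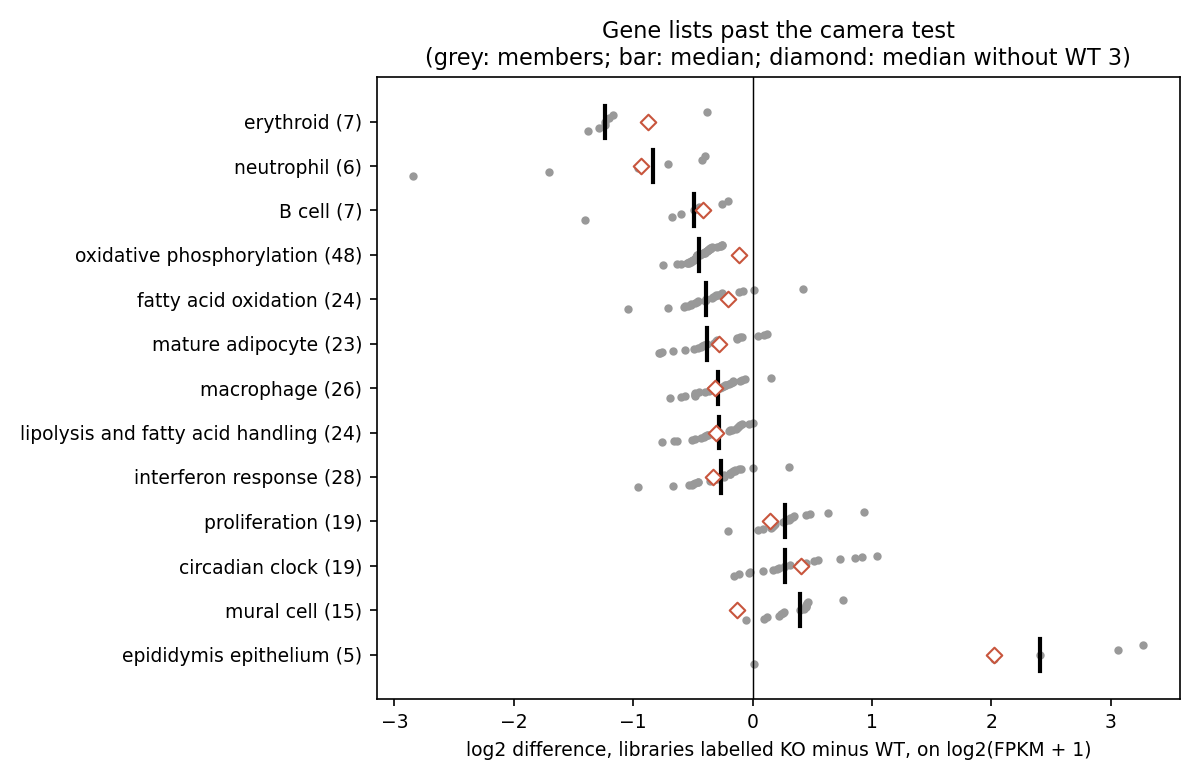
Log2 difference between the libraries labelled KO and WT for the tested members (grey points, number in brackets) of the 13 lists past the camera test, with the median (bar) and the median without WT 3 (diamond). The mural cell median went from 0.40 to -0.13 without WT 3, and the oxidative phosphorylation median from -0.45 to -0.12.

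The other 22 lists did not pass in the main setting, and some passed in an alternative. Without WT 3 immediate early and heat shock genes passed as lower (median -0.58, camera adjusted p = 1.83e-04). So did inflammatory mediators (median -0.26, 0.00753) and the unfolded protein response (median -0.13, 0.0092). Mesothelial genes passed as higher without WT 2 (median 0.25, camera adjusted p = 0.0265). In the main setting 8 of them were higher and 8 lower. The 3 with limma's unadjusted p under 0.05 were the keratins Krt19, Krt8 and Krt18. Like Epcam, Krt8 had more in WT 1 (20.4 FPKM) than in WT 2 and WT 3 (1.63 and 0.828 FPKM). Of 14 genes tied to adipocyte size 8 had higher values (median 0.08, camera adjusted p = 0.219), and Mest was the 1 past the threshold adjusted over the list alone. With quantile normalization that list passed as higher (median 0.29, camera adjusted p = 9.06e-04). Lipogenesis had a median of -0.35 (camera adjusted p = 0.0652), with Fasn, the fatty acid synthase, at -0.28. Without WT 3 the lipogenesis median was -0.11, and with a library left out Fasn had between -0.78 and 0.02. The list passed as lower without WT 2 (median -0.56, camera adjusted p = 1.76e-04), without KO 1 (0.0362) and KO 2 (0.0488), with median-ratio scaling (0.0406), with sample weights (0.00566) and with the ciliated-cell covariate (0.00139). Insulin signalling and glucose uptake had a median of -0.02 (camera adjusted p = 0.841), with the glucose transporter Slc2a4 at -0.31, and between -0.50 and -0.16 with a library left out. Thermogenic genes went both ways, 8 higher and 8 lower, with 6 past the threshold adjusted over the list alone. Among the 4 with the smallest p, Gk (1.78) and Esrrg (1.09) were higher, and Hoxc9 (-0.70) and Cox8b (-1.26, without WT 3 -0.88) were lower. Like Epcam, Gk had more in WT 1 (10.6 FPKM) than in WT 2 and WT 3 (2.2 and 2.86 FPKM), and so did Esrrg. Whether these calls lie in fat cells was not tested. Extracellular matrix, endothelial and adipose progenitor lists had medians of 0.08, 0.17 and 0.02. Adipose progenitor passed as higher with quantile normalization (median 0.14, camera adjusted p = 0.0247) and without WT 2 (median 0.14, camera adjusted p = 0.0146). The other 2 lists were called in opposite directions with single WT libraries left out. Without WT 3 extracellular matrix (median -0.22, camera adjusted p = 0.00753) and endothelial genes (median -0.21, camera adjusted p = 3.59e-04) were lower, and without WT 2 they were higher (medians 0.25 and 0.40, camera adjusted p = 0.00729 and 0.00913). In 8 lists the median, mean and test differed in sign, among them adipokines (median -0.23, mean 0.13). Lep had a log2 difference of -0.13, Pparg -0.33, Adgre1 -0.20, Ccl2 0.13, Col1a1 0.13 and Ppargc1a 0.01. With a library left out Lep ran from -0.55 to 0.36, Ccl2 from -0.26 to 0.38, Col1a1 from -0.42 to 0.44 and Ppargc1a from -0.07 to 0.06. Pparg ran from -0.47 to -0.12 and Adgre1 from -0.46 to -0.06. Tnf and Ucp1 were below the filter, with means of 0.461 and 0.0425 FPKM.

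Transcripts of other cell types separated libraries within the WT group. Foxj1, the master regulator of motile cilia, had 44.2, 43.2 and 20 FPKM in KO 1, KO 2 and KO 3 and 13.9 FPKM in WT 1, against 0.034 FPKM in WT 2 and a listed 0 in WT 3. The median multiciliated gene of WT 1 reached 44.5% of the mean of the libraries labelled KO, against 1.51% in WT 2 and 1.11% in WT 3. The list was chosen after the data were seen. Over log2(FPKM + 1) WT 1 correlated most closely with KO 3 (Pearson r = 0.986 across genes, which are not independent replicates). Its r was 0.9742 with KO 1 and 0.9745 with KO 2, above the 0.966 with WT 2 and 0.955 with WT 3.

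**Figure D3:**
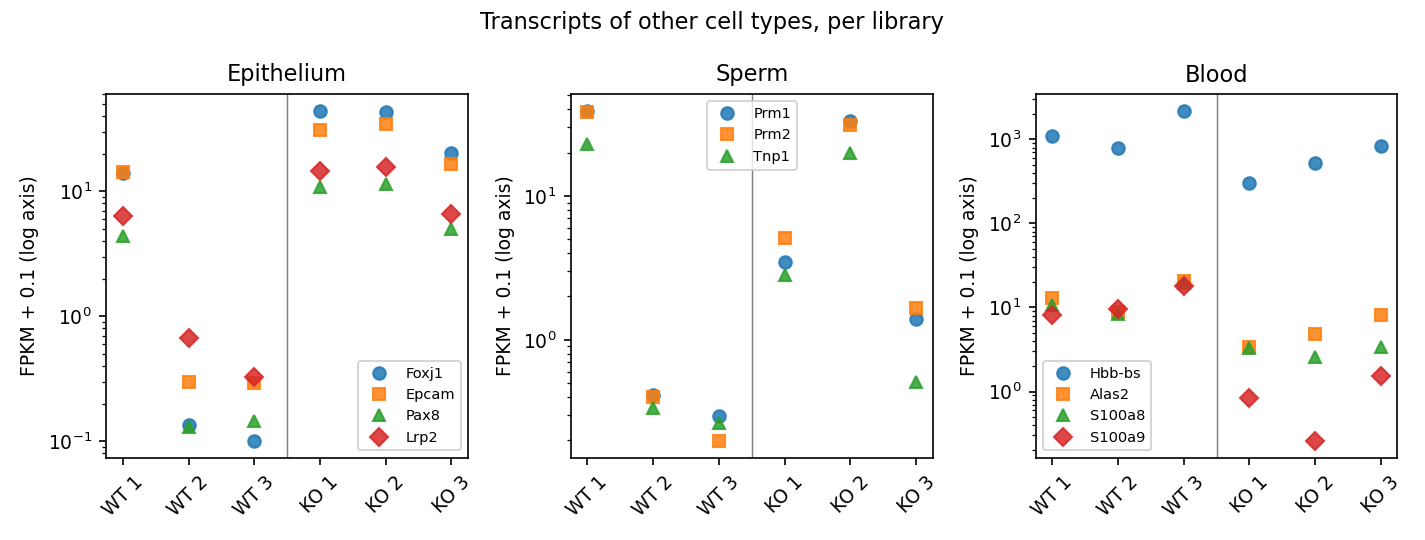
FPKM plus 0.1 on a log axis for genes of epithelium, sperm and blood in each of the 6 libraries. Foxj1 lay at 13.9 FPKM or more in WT 1, KO 1, KO 2 and KO 3 and at 0.034 FPKM or less in WT 2 and WT 3.

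WT 3 also stood apart by transcript length. Its median deviation from the gene mean was 0.76 on the log2 scale for transcripts under 500 nt and -0.26 for those over 7000 nt. The other 5 libraries lay between -0.19 and -0.08 for the shortest and between 0.03 and 0.10 for the longest transcripts. After a length and GC correction, chosen after the data were seen, 0 genes passed the adjusted threshold and 2163 had an unadjusted p under 0.05.

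**Figure D4:**
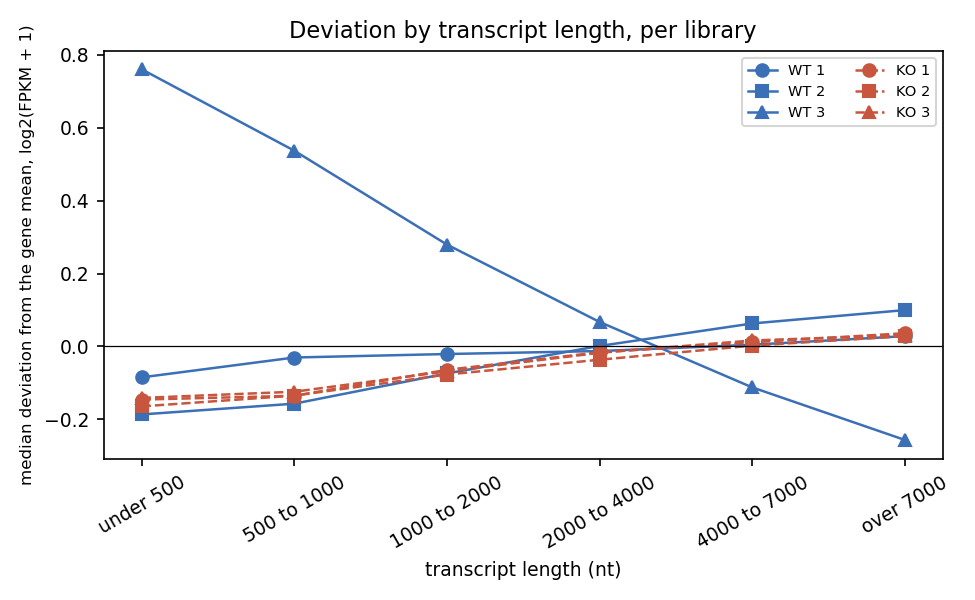
Median deviation of each library from the gene mean of log2(FPKM + 1), by transcript length in nt (solid lines: WT; dashed lines: labelled KO). WT 3 runs from 0.76 in the shortest to -0.26 in the longest class.

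Of the 53 other tested genes within 1 Mb of Zfp251, 0 passed the adjusted threshold and 7 had an unadjusted p under 0.05. That is a similar share to the 1700 of all 12539 tested genes. The direct neighbours, chosen after their values were seen, were Arhgap39, with a log2 difference of 0.45 (limma adjusted p = 0.223), and Zfp7, with 0.43 (limma adjusted p = 0.251).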

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

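The length and GC correction and the ciliated-cell covariate were chosen after the data were seen. The Zfp251 log2 difference was 0.72 and stayed positive in all settings, from 0.65 to 0.78 with a library left out. It passed the threshold without WT 1 (limma adjusted p = 0.0409, range 0.0367 to 1 over the alternatives) and with sample weights, where it was 0.64. It had no value at a mean of at least 5 FPKM, which leaves the gene out. No gene passed in any setting except sample weights, with 970 genes (511 higher, 459 lower), and without WT 1. Leaving out single libraries gave 0 to 482 genes, 0 to 469 higher and 0 to 13 lower. Of the 469 higher without WT 1, in 319 the FPKM of WT 1 was over 4 times that of WT 2 and of WT 3. Of all 12539 tested genes 389 had that pattern. WT 1 thus widened the WT spread of the 319 genes. The 469 held 38 of the 48 tested multiciliated genes and the 20 tested tubule epithelium genes. The sample weights were 4.02, 0.472 and 0.142 in WT 1, WT 2 and WT 3, so the weighted WT mean leaned on WT 1. In KO 1, KO 2 and KO 3 they were 3.15, 1.53 and 0.767. Whether this made the calls with sample weights was not tested. With the replicate number as a block, 0 genes and 15 lists passed, adding lipogenesis (camera adjusted p = 0.0289) and skeletal muscle (median -0.96, camera adjusted p = 0.034; without a block and without WT 3 median -0.07, 0.96), and the Zfp251 log2 difference was 0.72. No label says that the numbers pair the libraries. The correlations of same-numbered deviations were 0.228, -0.2 and 0.22, which cannot decide it, since differently numbered ones were not compared.

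The 13 lists became 0 with an estimated correlation and 0 with fry, and 14 to 18 with a library left out. The fatty acid oxidation, interferon response, erythroid and circadian clock lists passed in the other settings. Among lists past the threshold in the main or the alternative setting, those whose camera direction turned, with their medians (mature adipocyte, B cell and cholesterol synthesis kept the sign of theirs), the cause not tested: with quantile normalization mature adipocyte (-0.042); with sample weights extracellular matrix (-0.25); with the ciliated-cell covariate cholesterol synthesis (-0.26), macrophage (0.36), B cell (-0.10), endothelial (-0.31), epididymis epithelium (-0.20) and testis germ cell (-2.76). With libraries left out in turn, the medians ran from -0.34 (without WT 2, turned) to 0.013 for cholesterol synthesis. They ran from -0.22 to 0.25 for extracellular matrix, from -0.21 to 0.40 for endothelial and from -0.13 to 0.71 for mural cell, and all 3 turned without WT 3. Of 152 named genes besides Zfp251, 107 kept their sign in all settings. Depth is unknown beyond the relative values.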

Other observations

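The tests of explanations, the length and GC correction and the ciliated-cell covariate in this part were chosen after the results were seen, while the testis germ cell list, the pseudocounts, the left-out libraries and the sample weights were planned. Sperm transcripts followed another set of libraries than the ciliated genes. The protamine gene Prm1, which packs sperm DNA, had 39.2 FPKM in WT 1 and 33.3 FPKM in KO 2, against 3.4 FPKM in KO 1, 1.3 FPKM in KO 3, 0.312 FPKM in WT 2 and 0.195 FPKM in WT 3. The testis germ cell list did not pass (median 0.34, camera adjusted p = 0.143), but it passed as higher without WT 1 (median 1.52, camera adjusted p = 5.19e-05), without KO 3 (median 0.90, 0.0166), with a pseudocount of 0.1 (median 1.39, 0.0314) and after the length and GC correction (median 0.41, 0.0453). With the ciliated-cell covariate it passed as lower (median -2.76, camera adjusted p = 8.93e-32), and without KO 2 its median was -0.32 (camera adjusted p = 0.947). The covariate is partly confounded with group, and the camera p-value with it rests on sperm genes that moved together, not on spread between mice. Fast muscle genes, chosen like the globin gene Hbb-bs and the caput gene Wfdc8 after their values were seen, were found in WT 3, where Ckm, the muscle creatine kinase, had 10.3 FPKM and Tnnt3, a fast troponin, 11.6 FPKM. In the other 5 libraries Ckm was at 0.156 FPKM or less and Tnnt3 at 0.548 FPKM or less. The ratio of S100a9 to Hbb-bs was 0.725%, 1.21% and 0.816% in WT, and 0.245%, 0.0299% and 0.172% in the libraries labelled KO.

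Zfp251 RNA was higher in the libraries labelled KO. A length or GC trend is argued against, since the corrected log2 difference of 0.63 stayed above 0.36, the middle of the way to 0, by more than 2 standard errors of 0.11. RNA of admixed epithelium is argued against as well, because KO 3 and WT 1, with close ciliated scores of 2.11 and 1.92, differed by 2.75 FPKM in Zfp251, and the log2 difference was 0.62 with the ciliated-cell covariate. An exchange of the labels of both groups cannot be told apart from RNA that the allele leaves in place, since the lowest library labelled KO had 1.57 times the FPKM of the highest WT library and no other value in the labels marks genotype. A change in the RNA's stability or promoter use in the mutant stays open, as untested.

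Epithelial RNA was present in 4 of 6 libraries, with median log2 differences of 1.62 over 48 tested multiciliated genes and 2.39 over 20 tubule genes. Genotype as the only cause is argued against by WT 1, whose median multiciliated gene reached 44.5% of the KO mean. One epithelial source in different amounts is a candidate explanation. The test took the 61 multiciliated and tubule genes with at least 1 FPKM in WT 1. Their log2 ratios to WT 1 had SDs of 0.36, 0.29 and 0.23 in KO 1, KO 2 and KO 3. Genes under 1 FPKM in WT 1 were left out, so the SDs cannot show epithelial genes that WT 1 lacked. The caput of the epididymis is argued against as that source, since the highest caput gene, Wfdc8, averaged 1.43 FPKM over these 4 libraries against 30.3 FPKM for Foxj1. Of the 52 multiciliated genes 7 reached 1 FPKM in WT 2 or WT 3, as did 3 of 23 tubule genes, and a duct next to the fat pad with ciliated cells may be the source, which was not tested beyond these lists.

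Fat and immune gene lists were lower in the libraries labelled KO. Without WT 3 all 9 lists passed, and after the length and GC correction 8 did. These calls cannot weigh the length trend of WT 3 as the cause, because other groupings of the 6 libraries gave 9 to 19 lists. With an estimated correlation or fry 0 lists passed. The 9 medians stayed negative without WT 3, so their sign did not need that library. Without WT 3 the endothelial, extracellular matrix and mural cell medians were negative as well (-0.21, -0.22 and -0.13). A negative sign there therefore does not set the 9 lists apart. The oxidative phosphorylation median went from -0.45 to -0.12 without WT 3 and that of fatty acid oxidation from -0.39 to -0.20. The B cell call ended with the correction (camera adjusted p = 0.0536), where the median went from -0.49 (SD over 7 genes 0.40) to -0.43 (SD 0.37) and the mean z of the list from -1.74 to -1.59, while that of all genes, which camera sets it against, went from -0.14 to -0.38. The erythroid list lay apart from the endothelial median by -0.67 without WT 3 and passed with the ciliated-cell covariate, where its median was -0.53. That gap cannot decide on dilution, since the endothelial median itself went from 0.17 to -0.21 without WT 3. The call with the covariate cannot either, because other groupings gave calls too and the covariate is partly confounded with group. Dilution by epithelium is therefore not excluded as the whole cause for the erythroid list. For the neutrophil list (a gap of -0.73, but a median of -0.28 and camera adjusted p = 0.175 with the covariate) and the adipocyte lists (oxidative phosphorylation lay 0.0937 above the endothelial median without WT 3) it cannot be told apart from lower expression, and it stays open for macrophage and B cell genes, whose calls as lower also ended with the covariate. A difference by genotype in fat cell metabolism or in the blood held by the tissue may remain, as untested.

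The 6 libraries make 10 splits into 3 against 3, too few for a share under 0.05. The real split gave 0 genes past limma's adjusted threshold and so did the others, as 10 of 10 splits gave as many. At an unadjusted p under 0.05 it gave 1700 genes against 1222 in the highest other split, with 1 of 10 splits as large. It gave 13 lists past the threshold against 19 in the highest other, with 7 of 10 as large. With sample weights it gave 970 genes against 1871 in the highest other split, with 2 of 10 as large. That other split, WT 1, WT 3 and KO 2 against the rest, had weights that did not converge, and among the 7 splits whose weights converged the highest other count was 5. The weights of the real split leaned on WT 1 (4.02) over WT 2 (0.472) and WT 3 (0.142). Its count of 970 therefore does not stand for 3 equal WT libraries.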
